A study of Homo sapiens with 3 samples.

How the data were processed

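Single-cell RNA was measured in 3 libraries of HCT116 H2B-GFP cells, 1 each from the top channel without stretch, the top channel with stretch and the bottom channel with stretch. Per the labels' protocols, cells were detached with trypsin (0.25%, 5 min, 37 °C), sorted for GFP, and made into droplet 3′ libraries with a target of 10000 droplets and 12 PCR cycles. The deposited matrices hold raw UMI counts per gene and barcode, made with Cell Ranger. Its version, 7.0.0, was read from the file header of the not stretched top library only. The build is hg38 per the submitters' processing notes, and the annotation version was not given in the sources used here. Each matrix had 19912 features, none of them GFP, and listed barcodes with at least 500 UMIs: 26106 in the not stretched top, 25169 in the stretched top and 3513 in the stretched bottom library. All columns were used.

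Cells were kept with at least 500 genes, at least 1000 UMIs and at most 20% of UMIs from mitochondrially encoded genes. This left out 34.1%, 20.1% and 44.5% of barcodes in the order above. A UMI count of 0 allows up to 0.0141, 0.0142 and 0.0391 CPM in these libraries. No cells were removed as doublets in the main values. Scrublet marked 1, 1 and 2 cells and so did not work as a doublet caller here.

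UMIs were summed over the kept cells of each library and divided by the library total to give CPM. Comparisons used the log2 ratio of CPM with 1 CPM added, for genes with at least 10 CPM in either library. As each group had 1 library, a difference is described by its size, with a threshold of 1.5-fold, and no test was made. Fold sizes are ratios of CPM with exact conditional binomial 95% intervals, CPM intervals are exact Poisson and shares have Clopper-Pearson intervals. All of them cover counting error only. Where a gene had 0 UMIs in a library, the fold was computed against a floor of 3 counts. It is a lower bound only if UMIs are independent, which fails for genes carried by few cells.

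Before the data were examined, the design, the alternatives, 37 gene lists and the rule for named genes were fixed. The rule took the 12 highest and 12 lowest ratios of each comparison (5 and 5 in the third), leaving out mitochondrially encoded, ribosomal protein, LINC, clone-named and Y-linked genes and XIST. It added the 2 to 4 members of each list with the largest ratio in either direction, and EPCAM and VIM in every library. A list's median covers members with a mean of at least 1 CPM, and its percentile comes from 10000 random lists of the same size drawn within 20 bins of mean expression, as a description of these libraries. The median of all genes over that same minimum was −0.17 in the first comparison, −0.07 in the second and −0.24 in the third, and list medians are to be read relative to it.

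For phase shares, each cell was thinned to 3000 UMIs and shallower cells were left out. Phases were called with scanpy from the S and G2/M lists. For clusters, up to 5000 cells per library were normalised to 10000 per cell, and 2000 variable genes, 30 components, 15 neighbours and Leiden resolution 0.5 were used. Each other kept cell took the most frequent cluster among its 15 nearest of these cells. A cluster was called epithelial-like if at least 5 fixed epithelial markers reached 10 CPM and no other class had more. Clusters of very few cells were left unnamed. So were clusters of low UMIs for their library with no epithelial marker among their 10 leading genes. Gene coordinates and the share of a gene's last 1000 exonic bases that overlaps another gene on the same strand came from GENCODE release 29, which is on the same build.

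The alternatives were no cell filter, a stricter cell filter (2000 genes, 5000 UMIs, 10% mitochondrial), TMM and median of ratios scaling, totals without mitochondrial and ribosomal protein genes, equal cell weights, thinned cells, cells marked by Scrublet left out, equal phase weights, epithelial-like clusters only, 0.1 or 5 CPM added, a minimum of 1 or 50 CPM, a 2-fold threshold, other clustering settings and other thinning. Added after the data were seen were leaving out the highest Scrublet scores, the APOA1-high cluster, that cluster with all unnamed clusters, and genes with shared 3′ ends. TMM factors came from edgeR 4.0.16 in R 4.3.3. The rest used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9.

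The ratio step was tested on simulated data drawn from the real libraries' means, with 200 changed genes. For stretched top against not stretched top (8907 genes), 70 of 70 genes changed 2-fold and 70 of 70 changed 4-fold passed the threshold in the right direction, 0 of 60 changed 1.25-fold did, and 0 of 8707 unchanged genes did. The same shares held for stretched bottom against stretched top (8603 genes) and against not stretched top (8951 genes). Intervals held the true fold for 188, 193 and 190 of 200 genes. Both libraries of a pair were drawn from a shared mean with counting error only. The simulation therefore does not cover variation between chips or cells, or the choice of scaling.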

Results

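Single-cell RNA counts were analysed from 3 libraries of HCT116 cells, a human colorectal carcinoma line that here carried a histone H2B-GFP label. The cells had grown in a 2-channel organ-on-chip, a microfluidic culture device, and the stretched chips had been exposed to cyclic, peristalsis-like stretch for 6 days. GFP-positive cells were sorted from the top channel without stretch, from the top channel with stretch, and from the bottom channel with stretch, which holds the cells that had invaded. Each group had 1 library, so no difference below has a replicate check, no test between conditions was possible, and intervals cover counting error only. After filtering, the not stretched top library held 17206 cells and 212503735 UMIs, the stretched top library 20121 cells and 210814252 UMIs, and the stretched bottom library 1951 cells and 76641034 UMIs. The median kept cell had 10964, 9384 and 40387 UMIs in that order. The median share of UMIs from mitochondrially encoded genes was 9.64%, 10.4% and 4.09%. EPCAM, the epithelial adhesion molecule (ENSG00000119888, chromosome 2, 47345158 to 47387601, hg38), stood at 386 CPM in the not stretched top library, 389 CPM in the stretched top library and 501 CPM in the stretched bottom library.

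The first comparison, stretched top against not stretched top, addressed what stretch does to the tumor cells that stay in the top channel. Most genes differed little. RBM3, a cold-inducible RNA-binding protein (ENSG00000102317, chromosome X, 48574449 to 48579066), was 2.33-fold lower with stretch (95% interval 2.29 to 2.37), at 84.5 against 197 CPM. BST2, the interferon-induced membrane protein tetherin (ENSG00000130303, chromosome 19, 17402939 to 17405648), was 2.32-fold lower (2.27 to 2.36), at 75.3 against 174 CPM. DDIT4, a stress-induced inhibitor of mTORC1, was 2.22-fold lower (2.17 to 2.28), at 44.7 against 99.5 CPM. The vitamin D 24-hydroxylase gene CYP24A1 was 1.96-fold higher (1.84 to 2.08), at 15.2 against 7.76 CPM, and the copper chaperone gene ATOX1 was 1.72-fold higher (1.69 to 1.75), at 199 against 116 CPM.

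Interferon-stimulated genes were the fixed list with the lowest median. Of 23 measured members, 5 were at least 1.5-fold lower with stretch and 0 were higher, and the list median was −0.44 on the log2 scale against −0.17 for all measured genes, below all of 10000 random lists of matched expression. Under TMM or median of ratios scaling 1 member, BST2, stayed past 1.5-fold. IFIT1 stood at 92.9 against 143 CPM, ISG20 at 15.8 against 26.2 CPM and IFI44 at 13.7 against 22.0 CPM. In antigen presentation genes 1 of 13 members was at least 1.5-fold lower (HLA-F, 15.1 against 23.7 CPM), with a median of −0.30 at percentile 0.10 of the random lists. Of 19 hypoxia genes 5 were lower and 0 higher (3 and 1 under TMM scaling); ANKRD37 was 1.86-fold lower, the vasodilator peptide gene ADM 1.77-fold lower and ANGPTL4 1.58-fold lower, while the list median (−0.16) lay at percentile 49.0 and turned sign under TMM and median of ratios scaling. SLC2A3 and SLC2A1, both glucose transporter genes, lay on opposite sides: SLC2A3 was 1.79-fold lower, and SLC2A1 stood at 128 against 95.5 CPM.

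Immediate early genes had a median of −0.26 (percentile 0.02) with 0 of 22 members past 1.5-fold; FOSB stood at 43.0 against 61.0 CPM and JUNB at 137 against 194 CPM. Of 16 TGF-beta target genes, 2 were lower: the helix-loop-helix inhibitor genes ID3 (1.55-fold) and ID2 (1.54-fold), with a list median of −0.28. Of 20 unfolded protein response genes 3 were lower, among them DDIT3 (1.78-fold) and SESN2 (1.59-fold). The fatty acid synthesis regulator SREBF1 was 1.55-fold lower, and the taurine transporter gene SLC6A6, counted in the GABA list, was 1.55-fold lower. HLA-F, ANGPTL4, ID2, ID3, SESN2, SREBF1 and SLC6A6 were short of 1.5-fold under TMM and median of ratios scaling. The mechanosensor genes had a median of −0.30 (percentile 0.75) and the YAP/TAZ target genes of −0.25 (percentile 2.15), each with 0 members past 1.5-fold in either direction. Further genes at the lower end were SAMD5, HTR7, SSBP2, RGS9 and the glucocorticoid-responsive co-chaperone gene FKBP5, between 1.70-fold and 2.28-fold lower. FKBP5 was short of 1.5-fold under TMM and median of ratios scaling, and RGS9 under at least 1 alternative.

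The upper end of the lists held enterocyte differentiation genes (median 0.15, above all 10000 random lists), heat shock genes (0.11, percentile 99.2) and nuclear-encoded OXPHOS genes (0.10, percentile 99.5), with 0 members of any of these past 1.5-fold. Under TMM scaling 3 members of each of these lists were past 1.5-fold higher. FABP1 stood at 36.8 against 26.8 CPM, but most of its UMIs lay in a small APOA1-high cluster, and its log2 ratio was −0.05 without those cells. HSPE1 stood at 1556 against 1044 CPM and ATP5ME at 369 against 267 CPM. Metallothionein genes had a median of 0.31 over 4 members, with MT1X at 363 against 268 CPM. Relative to random lists, p53 target genes (median −0.02) lay above all 10000 too, and NF-kB and inflammatory genes (0.02) at percentile 99.99. Cholesterol synthesis genes (0.02) lay at percentile 99.93 and NRF2 and oxidative stress genes (0.04) at percentile 99.61. Of these members, 1 NF-kB gene was at least 1.5-fold higher and 1 p53 target gene at least 1.5-fold lower. Of 13 mitochondrially encoded genes 1 was past 1.5-fold, MT-ND3 (1.65-fold higher), beside a median mitochondrial share of 10.4% against 9.64%. This direction depended on the cell filter: over all barcodes the median share was 10.9% against 11.3%, and without a cell filter the list median moved from 0.15 to −0.16. The secreted chaperone gene CLU was 1.61-fold higher, and CITED1, RAB27B, KLRC2, WFDC3, DPM3, APOC3, PRF1 and MYH15 between 1.55-fold and 1.87-fold higher. APOC3 is a marker of the APOA1-high cluster as well, and its log2 ratio was 0.39 without those cells. MT-ND3, RAB27B, WFDC3, PRF1 and MYH15 were also short of 1.5-fold under at least 1 alternative. Of 35 named ratios past 1.5-fold in this comparison, 17 stayed past it under every alternative. KLRC2 belongs to a family of near-identical genes, so its value is uncertain. EMT lists held no member past 1.5-fold: mesenchymal genes had a median of 0.00 (percentile 99.7) and partial EMT genes of −0.06 (percentile 97.6), and under TMM scaling 2 partial EMT genes were past it. VIM, an intermediate filament gene of mesenchymal cells, stood at 7.89 against 5.94 CPM, and S100A4 at 3154 against 2510 CPM.

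Among 9119 genes with at least 10 CPM in either library, 16 were at least 1.5-fold higher with stretch and 54 at least 1.5-fold lower, and at 2-fold these were 0 and 6. The median gene was shifted by −0.16 on the log2 scale under scaling to total counts, and the split depended on it: TMM scaling gave 70 higher and 10 lower, median of ratios 76 and 10, and totals without mitochondrial and ribosomal protein genes 24 and 44.

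**Figure D1:**
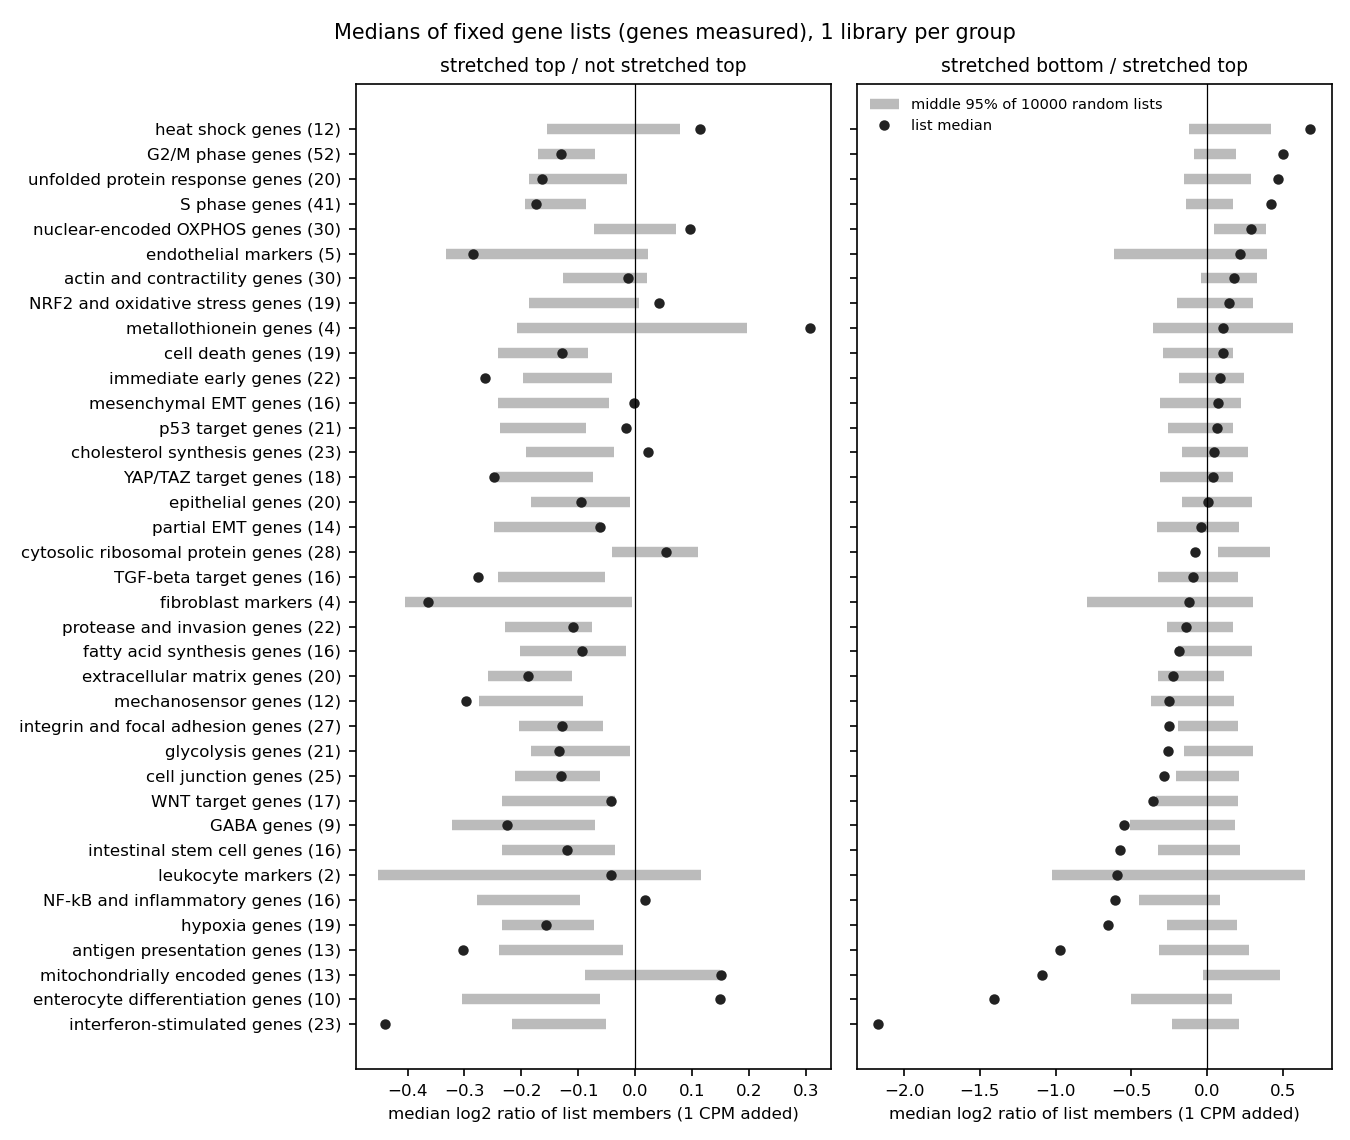
Median log2 ratio (1 CPM added) of the members of each of the 37 fixed gene lists, with the number of measured genes in parentheses, for stretched top over not stretched top (left) and stretched bottom over stretched top (right), with 1 library per group. Points are list medians and grey bars the middle 95% of 10000 random lists of the same size and expression; interferon-stimulated genes lie lowest in both panels, at −0.44 and −2.17, and heat shock genes highest on the right, at 0.68. Under TMM scaling or median of ratios, which shift all genes of the left panel upward, some lists below 0 there come to lie above 0.

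The second comparison, stretched bottom against stretched top, addressed how cells that had invaded the bottom channel differ from those that stayed in the top channel under stretch. All 23 interferon-stimulated genes measured were at least 1.5-fold lower in the bottom library, with a list median of −2.17, below all 10000 random lists. IFI27, an interferon-induced mitochondrial protein gene (ENSG00000165949, chromosome 14, 94104836 to 94116698), stood at 18.0 against 562 CPM, 31.3-fold lower (29.7 to 33.0). IFI6 (ENSG00000126709, chromosome 1, 27666061 to 27672218) stood at 50.4 against 1066 CPM, 21.2-fold lower (20.5 to 21.8). IFIT1 was 20.2-fold lower (18.2 to 22.5), BST2 18.5-fold lower (16.6 to 20.8), and OAS1, a double-stranded RNA sensor gene, 53.5-fold lower (36.4 to 82.0) from 26 UMIs. With every cell thinned to 3000 UMIs, the median cell held 2 UMIs of this list in the bottom library against 15 in the stretched top and 21 in the not stretched top library.

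Antigen presentation genes were lower as well: 12 of 13 members passed 1.5-fold, with a median of −0.97. The immunoproteasome subunit gene PSMB9 was 4.89-fold lower (4.53 to 5.27), the MHC class I transactivator gene NLRC5 3.73-fold lower and HLA-B 2.49-fold lower. Of 16 NF-kB and inflammatory genes 9 were lower and 0 higher (median −0.61, and between −0.82 and −0.26 over the alternatives), among them RELB (1.84-fold). Of 19 hypoxia genes 12 were lower and 0 higher, with a median of −0.65. NDRG1 was 3.08-fold lower (2.98 to 3.18), the MYC antagonist gene MXI1 2.97-fold lower, the mitophagy receptor gene BNIP3L 2.93-fold lower and SLC2A1 2.40-fold lower. In the glycolysis list 6 of 21 members were lower and 1 higher (median −0.26): ALDOC was 4.11-fold lower, and ALDOA was 2.21-fold higher but shares 76.3% of its last 1000 exonic bases with another gene, so its counts are uncertain.

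Cell cycle genes were higher in the bottom library. Of 52 G2/M phase genes 21 were at least 1.5-fold higher and 0 lower (median 0.50), and of 41 S phase genes 11 were higher and 0 lower (median 0.42), both above all 10000 random lists. The mitotic kinesin gene KIF23 was 2.00-fold higher (1.94 to 2.07), CDK1 1.84-fold higher and the thymidylate synthase gene TYMS 1.84-fold higher. At 3000 UMIs per cell, 48.8% of bottom cells were called G2/M (46.4 to 51.2), against 29.3% (28.7 to 29.97) in the stretched top and 27.6% (26.9 to 28.3) in the not stretched top library. S phase calls were 28.0% (25.9 to 30.2), 20.6% (19.996 to 21.2) and 21.4% (20.8 to 22.1), and G1 calls 23.2% (21.2 to 25.2), 50.1% (49.4 to 50.8) and 51.0% (50.2 to 51.8). Thinning left out 242, 1205 and 1507 cells. Without thinning G2/M calls were 49.7%, 30.6% and 29.1%, and under a stricter cell filter 50.3%, 43.2% and 38.6%, with G1 calls of 22.1%, 30.3% and 34.2%. Under that filter the list medians were 0.21 for G2/M and 0.13 for S phase genes, and the part that free RNA has in these calls was not measured. Over all alternatives the G2/M median lay between 0.14 and 0.65 and the S phase median between 0.13 and 0.54.

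**Figure D2:**
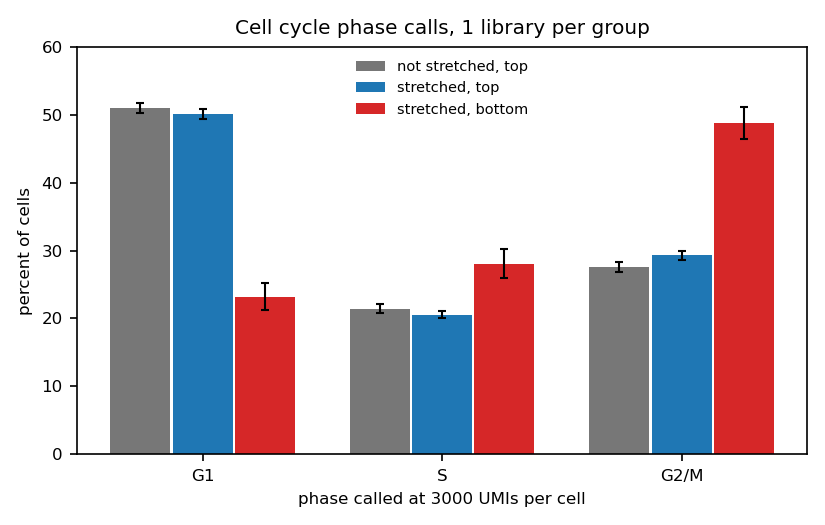
Percent of cells called G1, S or G2/M in each library after thinning every cell to 3000 UMIs; bars start at 0 and error bars are exact 95% binomial intervals for counting error only, 1 library per group. G2/M calls were 48.8% in the stretched bottom library against 29.3% and 27.6% in both top libraries.

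Heat shock genes had the highest median of the lists (0.68, above all 10000 random lists), with 8 of 12 members higher and 0 lower: DNAJB4 was 2.96-fold higher, DNAJB1 2.12-fold and the constitutive chaperone gene HSPA8 1.96-fold. HSPA1B was 5.70-fold higher (5.53 to 5.87) but has a near-identical copy, so its value is uncertain. Of 20 unfolded protein response genes 6 were higher and 0 lower (median 0.46), including TRIB3 (2.02-fold), CRELD2 (1.92-fold) and the calreticulin gene CALR (1.63-fold). The list of 13 mitochondrially encoded genes went the other way, with 10 lower and 1 higher and a median of −1.09; MT-CYB was 3.61-fold lower, beside a median mitochondrial share of 4.09% against 10.4%. Nuclear-encoded OXPHOS genes were 5 of 30 higher and 0 lower (median 0.29, percentile 77.3), with ATP5ME 1.82-fold higher.

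WNT target and stem cell genes had low medians, with DKK1 as an exception. DKK1, a secreted WNT antagonist (ENSG00000107984, chromosome 10, 52314296 to 52318042), was 3.45-fold higher (3.396 to 3.496), at 537 against 156 CPM. The WNT target list had 1 of 17 members higher and 6 lower (median −0.36), with NOTUM 3.08-fold and EPHB2 2.81-fold lower. Of 16 intestinal stem cell genes 8 were lower and 0 higher (median −0.58), among them MSI2 (1.64-fold) and CD44 (1.58-fold). Of 9 GABA genes 4 were lower and 1 higher (median −0.55, and between −0.71 and −0.17 over the alternatives), and the 1 higher member, GABARAP, shares 51.6% of its last 1000 exonic bases with another gene.

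EMT, adhesion and invasion lists had members on both sides. VIM (ENSG00000026025, chromosome 10, 17228259 to 17237593) was 3.41-fold higher in the bottom library (3.19 to 3.64), at 26.9 against 7.89 CPM, while S100A4 was 1.89-fold lower, and the mesenchymal list had 1 of 16 members higher and 5 lower. In partial EMT genes 3 of 14 were higher, TNFRSF12A 2.39-fold and the urokinase gene PLAU 1.63-fold among them, and 2 lower, including the integrin gene ITGB4 (1.71-fold). Of 20 epithelial genes 4 were lower and 0 higher, among them the transcription factor gene ELF3 (2.91-fold), CLDN3 (1.62-fold) and the E-cadherin gene CDH1 (1.56-fold), whose log2 ratio of −0.62 moved to −0.56 under median of ratios scaling and to −0.36 without the APOA1-high cluster. Medians of these lists lay near 0 (0.07, −0.04 and 0.01), and their signs turned under another scaling. Protease and invasion genes were 2 of 22 higher and 7 lower, with CTSL 1.80-fold higher and TIMP2 2.98-fold lower. Integrin and focal adhesion genes were 1 of 27 higher and 5 lower (TNS3 3.01-fold lower, ITGB1 1.53-fold higher), cell junction genes 1 of 25 higher and 7 lower (TJP3 2.65-fold lower), and actin and contractility genes 4 of 30 higher and 1 lower (RHOB 2.12-fold higher, ACTB 1.54-fold higher). YAP/TAZ target genes were 2 of 18 higher, AMOTL2 (2.22-fold) and the tissue factor gene F3 (1.98-fold), with 0 lower, and mechanosensor genes 3 of 12 lower with 0 higher.

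Of the remaining lists, extracellular matrix genes were 5 of 20 lower with 0 higher, fatty acid synthesis genes 3 of 16 lower with 0 higher, and cholesterol synthesis genes 1 of 23 higher (CYP51A1, 4.11-fold) and 3 lower. Immediate early genes were 5 of 22 higher and 5 lower (JUN 1.84-fold higher, KLF2 1.85-fold lower), NRF2 and oxidative stress genes 4 of 19 higher and 3 lower (HMOX1 2.12-fold higher), p53 target genes 1 of 21 higher and 3 lower, TGF-beta target genes 1 of 16 higher and 2 lower, and cell death genes 1 of 19 higher and 2 lower. Metallothionein genes were 1 of 4 higher (MT2A, 1.70-fold) and 1 lower. Cytosolic ribosomal protein genes had 0 of 28 members past 1.5-fold, with a median of −0.08 that lay at percentile 0.02. Of the markers of other cell types, 1 of 5 measured endothelial genes was higher, 1 of 4 fibroblast genes lower, and 1 of 2 leukocyte genes higher and 1 lower.

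Several of the genes with the lowest ratios marked a small group of cells in the top libraries. APOA1, an intestinal and hepatic apolipoprotein gene, stood at 0.796 against 108 CPM, 135-fold lower in the bottom library (105 to 177), APOA2 was 399-fold lower (228 to 772) and APOE 36.0-fold lower. FABP1, AGR2 and APOC3 had 0 UMIs in the bottom library and were 940.1-fold, 521-fold and 460.1-fold lower against a floor of 3 counts. TTR had 1 UMI there and a ratio of 1678, with an interval of 301 to 66297. In the stretched top library 92.6% of APOA1 UMIs and 94.0% of FABP1 UMIs lay in 1 cluster of 390 cells, described further in the closing section. The folds and intervals of such genes treat UMIs as independent, although few cells carried them, so they do not bound the difference. By cells, the cluster held 1.94% of stretched top cells and 0 of 1951 bottom cells, where a limit of 3 counts allows up to 0.154%. The enterocyte differentiation list (7 of 10 lower, median −1.41, with 4 members at 0 UMIs in the bottom library) moved to −0.33 without those cells. The fibronectin gene FN1, 7.56-fold lower over all cells, had a log2 ratio of 0.16 without them, and SLC2A3 moved from −1.84 to −0.79.

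The genes with the highest ratios besides HSPA1B were SULT6B1 (ENSG00000138068, chromosome 2, 37167820 to 37196598), 10.2-fold higher (9.41 to 11.1), JSRP1 (13.6-fold), EVI5L (6.41-fold), NME2 (6.04-fold), PAM16 (5.71-fold), HIST1H2AJ (4.73-fold), KRTAP2-3 (4.45-fold), ZC3H3 (3.95-fold), C11orf98 (4.64-fold), CPLX2 (4.84-fold) and HIST1H3J (4.35-fold). NME2, PAM16, C11orf98 and HIST1H3J share between 44.3% and 69.2% of their last 1000 exonic bases with another gene, and HIST1H2AJ and KRTAP2-3 belong to families of near-identical copies, so these values are uncertain.

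Among 8870 genes with at least 10 CPM in either library, 703 were at least 1.5-fold higher in the bottom library and 977 at least 1.5-fold lower, and at 2-fold these were 113 and 300. Median of ratios scaling gave 945 higher and 809 lower, totals without mitochondrial and ribosomal protein genes 396 and 1696, and a stricter cell filter 352 and 895. Of 123 named ratios past 1.5-fold, 81 stayed past it under every alternative. Among those above that did not were CDK1, TYMS, CALR, MSI2, CD44, PLAU, ITGB4, CLDN3, CDH1, FN1, ITGB1 and ACTB, with ITGB1 at 0.47 and ACTB at 0.49 under totals without mitochondrial and ribosomal protein genes. Of 8 list medians past 1.5-fold 3 stayed past it: those of interferon-stimulated, antigen presentation and mitochondrially encoded genes.

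**Figure D3:**
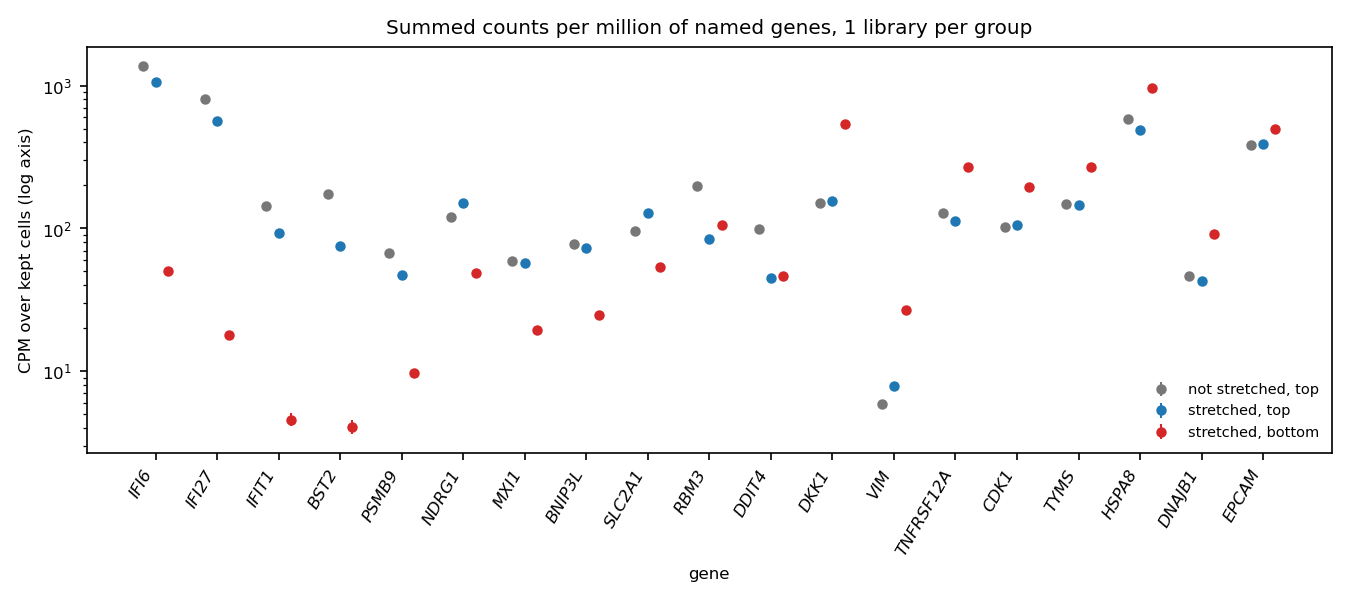
CPM on a log axis of 19 named genes over the kept cells of each library, 1 library per group; error bars are exact 95% Poisson intervals for counting error only and are mostly smaller than the points. IFI6 stood at 1066 CPM in the stretched top and 50.4 CPM in the stretched bottom library, and DKK1 at 156 and 537 CPM.

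The third comparison, stretched bottom against not stretched top, joins both differences and shares a library with each of the others, so it is not independent of them. IFI27 was 44.9-fold lower (42.5 to 47.3) and BST2 42.9-fold lower (38.4 to 48.2) in the bottom library, and 23 of 23 interferon-stimulated genes and 13 of 13 antigen presentation genes were at least 1.5-fold lower, with medians of −2.58 and −1.25 against −0.24 for all measured genes. Of 19 hypoxia genes 13 were lower (median −0.99). Heat shock genes (9 of 12 higher, median 0.92), G2/M phase genes (16 of 52 higher, median 0.39) and S phase genes (5 of 41 higher, median 0.27) each lay above all 10000 random lists. With equal phase weights the G2/M median was −0.02 and the S phase median −0.03. Phases were called from these same lists, so equal weights lower these medians by construction, and no cause is read from it. SULT6B1 was 21.4-fold higher (19.1 to 24.1), JSRP1 21.2-fold, the glutamate receptor subunit gene GRIA4 9.88-fold, NME2 5.89-fold and EVI5L 5.72-fold higher, and VIM was 4.53-fold higher (4.22 to 4.86). APOA1 was 174-fold lower, APOA2 389-fold lower and FABP1, with 0 UMIs, 685-fold lower against the floor of 3 counts. Most of their UMIs in the not stretched top library lay in 388 cells of the APOA1-high cluster, so these folds are not bounds either.

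Of 9218 genes, 627 were at least 1.5-fold higher and 1910 at least 1.5-fold lower in the last of these comparisons, with a median gene at −0.18. TMM scaling gave 1355 higher and 1020 lower, median of ratios 1556 and 914, and totals without mitochondrial and ribosomal protein genes 476 and 2786.

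Clustering of all kept cells gave 10 clusters, of which 6 were called epithelial-like and 4 had no name. The unnamed clusters had 10 to 12 epithelial markers at 10 CPM, against 12 to 14 in the named ones. They went unnamed for low UMIs, with the median cell at 0.081 to 0.324 of its own library's median, and those of 9 and 8 cells for their size as well. A single epithelial-like cluster held 82.3% of bottom cells (80.5 to 84.0), 0.268% of stretched top cells and 0.128% of not stretched top cells. As it came almost wholly from 1 library, it cannot be separated from that library. Most other top-channel cells spread over 4 epithelial-like clusters that together held 2.10% of bottom cells. An unnamed cluster of low UMI counts held 7.38% of not stretched top, 4.23% of stretched top and 9.23% of bottom cells. In those 4 clusters of the stretched top library IFI6 stood between 939.8 and 1349 CPM, against 42.5 CPM in the cluster of bottom cells.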

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

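No test was run on the result of this part, and it was looked for among barcodes that the main comparisons left out and only the alternative without a cell filter used. In the stretched bottom library 36.1% of barcodes (34.5 to 37.7, Clopper-Pearson) had more than 20% of their UMIs from mitochondrially encoded genes, against 27.0% (26.5 to 27.6) in the not stretched top library and 13.6% (13.1 to 14.0) in the stretched top library. The signal lies in data outside the main measurement and above the control level. Left-out bottom barcodes were shallow: all 3513 barcodes held 79984521 UMIs, and the 1951 kept cells held 76641034 of them. Whether the left-out barcodes are invaded cells was not tested. The bottom cells that were kept had the lowest median mitochondrial share of the 3 libraries, 4.09%.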

How the results depend on the processing

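The alternatives without the APOA1-high cluster, without the highest Scrublet scores and without genes with shared 3′ ends were chosen after the data were seen. Of 111 list medians, 16 were past 1.5-fold, and 0 of these changed sign under any alternative run, while 44 of the 111 did under at least 1. Of 431 named gene ratios 281 were past 1.5-fold, and 1 of these changed sign: FN1 in stretched bottom against stretched top, at 0.16 without the APOA1-high cluster, whose cells carry its UMIs. Under every alternative 180 of the 281 and 8 of the 16 stayed past 1.5-fold. The interferon median of that comparison lay between −2.68 and −1.78. Counts moved by more than 1.5 times as follows, with stretched top against not stretched top first. TMM scaling gave 70 higher and 10 lower, median of ratios 76 and 10, thinned cells 86 lower, 0.1 CPM added 83 lower and 5 CPM added 10 higher and 18 lower. A minimum of 1 CPM gave 26 and 123, of 50 CPM 7 and 14, and a 2-fold threshold 0 and 6. In stretched bottom against stretched top a stricter cell filter gave 352 higher, totals without mitochondrial and ribosomal protein genes 396 higher and 1696 lower, a minimum of 1 CPM 1842 lower, of 50 CPM 436 and 230, and a 2-fold threshold 113 and 300. In stretched bottom against not stretched top the stricter filter gave 387 higher, TMM 1355 and 1020, median of ratios 1556 and 914, a minimum of 1 CPM 3303 lower, of 50 CPM 445 lower, and a 2-fold threshold 149 and 613. Minimums and the fold threshold change the counts by construction, as does a scaling that shifts all genes; for the other settings the cause was not tested. Splits also moved by over 10 points with equal cell weights (961 higher and 665 lower, bottom against stretched top, and 704 and 1281, bottom against not stretched top) and with thinned cells (985 and 810, bottom against stretched top). Phase shares moved beyond their intervals in the top libraries. In the not stretched top library S was 27.2% under the stricter filter, and G2/M was 38.6% under it, 29.1% without thinning and 29.7% at 1500 UMIs. In the stretched top library S was 26.5%, 18.8% and 19.2% and G2/M 43.2%, 30.6% and 30.9% under the same settings, and the cause was not tested. Depth limits the bottom library most, where 0 UMIs allow 0.0391 CPM.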

Other observations

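Some tests were chosen only after the result was seen. For the interferon genes these were the tests of APOA1-high cells, depth and phase. For the APOA1-high cells they were the final tests of an HCT116 state and of doublets (with the simulated ones), which followed a first pooled test. The test of shared 3′ ends was chosen afterwards as well. The histone genes and the unnamed cluster were also singled out after their values were seen.

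Interferon-stimulated genes were lower in the stretched bottom library than in the stretched top library, with a list median of −2.17. Cell cycle phase is argued against as the cause, since the median was −2.11 with equal phase weights. In the stretched top library the list took 0.232% of UMIs in the APOA1-high cells, against 0.502% to 0.679% in the main top clusters. These cells lower the top level, so leaving them out could not weaken the difference, and the median of −2.18 without them decides nothing. With every cell thinned to 3000 UMIs the median was −2.17. Thinning keeps each cell's expected proportions, so this argues only against a heavier weight of deep cells in the sums. Selection of cells that were already interferon-low stays open: 1.75% of not stretched top cells held no more list UMIs than the median bottom cell. Among cells of named clusters other than the APOA1-high cluster 0.939% did. Part of this fall may come from leaving out the APOA1-high cells, in which the list took 0.227% of UMIs in that library. In the stretched top library, which the list median is set against, these shares were 3.29% and 2.62%. A batch that coincides with the bottom channel cannot be told apart from invasion, as there was 1 library per group. A bottom library made on another day would test the batch, but it would not test invasion itself, which also stays open and untested.

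APOA1-high cells made up 2.26% of not stretched top cells (388 cells), 1.94% of stretched top cells (390 cells) and 0 of 1951 bottom cells. A limit of 3 counts allows up to 0.154% there, and the Clopper-Pearson upper limit is 0.189%. A pooled test, fixed before its result was seen, counted genes of at least 100 CPM in the other named clusters that lay under 10% of that level in this cluster. It found 0 of 961, which met what both an HCT116 state and doublets had been set to predict, but pooling hides a mixture of cells. After that result, tests per cell with new bounds replaced it for doublets. For an HCT116 state the pooled count was kept and read together with the share per cell. In the stretched top library 55.1% of these cells (50.04 to 60.1) lay under 10% of the level of 25 genes, chosen in the not stretched top library as those lowest in this cluster relative to the other top clusters. Doublets simulated by adding a cell of those clusters to each of these cells, with 25 genes chosen again by that rule, gave 0 of 390 under 10% and a median of 62.3%, which argues against doublets for all of them. For the 35.6% of cells at 25% or more of that level doublets may be the cause, as their median UMIs were 1.56 times those of the cells under 10% (17740 against 11339). An intestinal epithelial cell of another origin is a candidate source, with 19 of 20 brush border, lipoprotein and enterocyte genes at least 3-fold higher, among them TSPAN8 (260.2 against 0.600 CPM), DPP4 (147 against 6.69 CPM) and APOB (145 against 0.120 CPM), but the GFP sort would remove cells without the label, and an HCT116 state stays open. The list does not settle the origin, since genes known from liver were high there too: APOA1, APOA2, TTR, APOE and VTN were among its 10 leading genes, and in the stretched top library AFP stood at 155 CPM and ALB at 55.7 CPM, against 0.190 and 0.180 CPM in other cells.

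Genes with at least 50% of their last 1000 exonic bases shared with another gene were higher in the bottom library, with a median of 0.28 over 86 genes, 31 of them at least 1.5-fold higher and 8 lower. Random sets of like expression lay between −0.18 and 0.05. Gene length is argued against, since an excess of 0.30 was left with length matched. Reads shared with an overlapping gene, counted differently in this library, may be the cause, and no biological explanation was tested.

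Histone-cluster genes were higher in the bottom library than in the stretched top library: 25 of 36 were at least 1.5-fold higher and 0 lower, with a median of 1.04, and of 0.90 with equal phase weights. Many are near-identical copies, so single values are uncertain. By gene length, medians in that comparison were 0.19 under 10 kb, 0.10 from 10 to 50 kb, −0.16 from 50 to 200 kb and −0.24 above that.

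An unnamed cluster of 181 cells held 109 bottom cells (5.59%), 48 not stretched top cells and 24 stretched top cells. In its bottom cells 7 of 18 fixed endothelial markers reached 10 CPM, against 2 in the cluster that held most bottom cells: EGFL7 stood at 107 CPM, ANGPT2 at 49.8, ERG at 48.1, VWF at 17.2, ENG at 17.2, EMCN at 15.5 and PECAM1 at 12.9. EGFL7 stood at 118 CPM in the other cluster as well. In the bottom cells of the unnamed cluster PECAM1 rested on 15 UMIs (7.21 to 21.3 CPM) and EMCN on 18 (9.17 to 24.4 CPM), so both intervals reach under 10 CPM. The remaining endothelial markers lay there between 0 CPM (CLDN5) and 9.45 CPM (MMRN1), with 7 UMIs for CDH5 and 1 for KDR. The same cells held EPCAM at 299 CPM and the fibroblast markers COL1A1 at 15.5 and FBN1 at 14.6 CPM, and 12 epithelial markers reached 10 CPM over the whole cluster, so the markers do not settle what these cells are. Of the bottom cells, 41 (2.10%) lay in the 4 epithelial-like clusters that held most top cells, and the interferon list took 0.302% of their UMIs against 0.107% in the main bottom cluster.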
